A study of Homo sapiens with 12 samples.

How the data were processed

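Ribosome footprints were measured in 12 libraries of A375 cells, in 4 groups of 3 libraries: control or FTSJ1 knockout, each at 0 or 30 nM sodium selenite. Per the labels, cells were snap-frozen and lysed with cycloheximide and tigecycline, the lysate was digested with RNase I, ribosomes were collected by ultracentrifugation, fragments of 17 to 40 nt were selected on a gel, and ribosomal RNA was depleted. The reverse transcription primer carried molecular identifiers, but whether they were used in counting is not stated. Per the labels the authors used Trim Galore 0.6.10, STAR 2.7.9a and DESeq2 with the GRCh38 build, with no role or order given, and the counting tool, the annotation and the read lengths kept are not stated.

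The authors deposited a table of raw footprint counts per gene, whole numbers from 0, for 13074 genes, 16 of which had no count in any of the libraries. They also deposited a table of normalized signal, which was checked to be the raw counts divided by 1 factor per library. The factors were 0.363 to 0.370 times those computed by DESeq2 over these libraries alone. Library totals were 520989 to 1543627 counts with a median of 1336000. These totals set the precision of each value: 3 counts, the limit used for a gene with none, correspond to 1.97 to 5.99 CPM in single libraries, a limit that covers counting error only. Gene symbols were matched to a GRCh38.p14 gene table, 12978 by symbol and 65 by synonym, with 31 unmatched, and coordinates were taken from it. No genome sequence was used.

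Raw counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 10467. Libraries were scaled by TMM, and quasi-likelihood models with robust dispersion were fitted to all libraries, with 1 coefficient per group. Tested were 5 contrasts: knockout versus control without and with selenite, selenite versus none in control and in knockout cells, and the interaction of knockout and selenite. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic and are approximate, and CPM values use TMM-scaled library sizes. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples. The replicate numbers were treated as numbers shared by name, with a blocked fit as an alternative. Where a group held 1 to 3 counts of a gene, the ratio of counts per depth is given with its exact Clopper-Pearson 95% interval. The number of genes was also counted under other assignments of the libraries to the groups, for the interaction by 100 draws within each genotype and by all 20 assignments within 1 genotype. The test was checked on simulated data with spiked changes of 1.5-fold, 2-fold and 4-fold. Recovery depends on how many genes are called, since this sets the adjusted threshold. The simulations called 78 to 137 genes, so their shares do not carry over to comparisons with far more or fewer calls. False calls were 7 of 134 and 10 of 119 for the knockout without and with selenite. They were 9 of 137 and 5 of 118 for selenite in control and knockout cells and 3 of 78 for the interaction. Simulated genes varied independently, without any trend shared by genes within a library.

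Gene lists, 23 in all, were fixed before the data were examined, as were the comparisons, their tests and most of the other settings tried. They were selenoproteins, stress-related and housekeeping selenoproteins, selenocysteine machinery, cysteine homologues, tRNA modification enzymes, NRF2 targets, ATF4 targets, unfolded protein response, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, cholesterol synthesis, ferroptosis regulators, melanocyte differentiation, dedifferentiated melanoma, MAPK output, cell cycle, p53 targets, interferon response, hypoxia and glycolysis, metallothioneins and heat shock, other cell type markers, and mitochondrially encoded proteins. None of the 13 mitochondrially encoded genes is in the table, so that list was not tested. Of 25 selenoprotein genes 19 are in the table and 18 were tested. Lists with at least 3 tested members were compared with all other genes by camera at a preset correlation between genes of 0.01, adjusted over the 22 lists within a contrast, and again with an estimated correlation. The median log2 fold change is given for each list, with the number of members that passed over all genes and when adjusted over the list alone.

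Genes were named by a rule fixed before the data were examined. It took FTSJ1, every tested selenoprotein gene, the 10 largest rises and falls per contrast among genes past the threshold with a mean of at least 10 CPM and no overlap between the groups (no such condition for the interaction), up to 4 members per list past the threshold or 2 where none passed, and the 5 highest and lowest genes called in both knockout comparisons. Unnamed loci and pseudogenes were passed over. The genes printed were selected from those the rule names after their values were seen.

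Alternatives planned beforehand were size factors by relative log expression, library totals only, DESeq2 1.42.0, no filter on low counts, a stricter filter of 10 CPM, only the groups compared, a replicate block, limma on the authors' normalized table (log2 with a pseudocount of 1), an estimated correlation for the lists, and leaving out each library in turn. Added after the data were seen were fits without both shallow libraries (knockout with selenite, replicates 2 and 3), with every library thinned to the smallest total, with genes of identical counts taken once, with a covariate for a gradient between control libraries, and with the trend on gene density (genes within 1 Mb) removed from each library. Figures were drawn with matplotlib 3.10.9.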

Results

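Ribosome footprints, the stretches of mRNA that a translating ribosome protects from nuclease, were counted per gene in 12 libraries of A375 cells, an established human melanoma line. The libraries fell into 4 groups of 3: control and FTSJ1 knockout cells, each without selenite and with 30 nM sodium selenite, a source of selenium. FTSJ1 is a methyltransferase that adds methyl groups to the ribose of anticodon-loop nucleotides in tRNAs, and the stated aim was to follow selenoprotein translation when the methylated wobble uridine of the selenocysteine tRNA was lost. Selenocysteine, the amino acid that defines selenoproteins, is inserted at UGA codons. Footprints were counted over whole genes, so those before and after a UGA codon were not separated and its decoding was not measured. The labels name a single knockout line, so the loss of FTSJ1 and any other difference of that line from control cannot be told apart. Only footprints were used here, so a change in mRNA level and a change in its translation were not separated.

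The library totals were 1378961 to 1497309 counts in control cells without selenite, 951567 to 1321859 in control cells with selenite, 1114731 to 1493468 in knockout cells without selenite and 520989 to 1543627 in knockout cells with selenite. In the last group, replicates 2 and 3 held 636920 and 520989 counts, the lowest totals of the 12 libraries. These shallow libraries also had the highest values on the second principal component of log2 CPM (counts scaled to a common library size), at 18.2 and 36.9 against -34.2 to 12.5 for the other 10 libraries. Their counts on histone genes were 84044 and 89954 CPM before TMM scaling, against 50608 to 71690 in the others. The first component, which carried 49.4% of the variance, separated all 6 knockout libraries from all 6 control libraries.

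**Figure D1:**
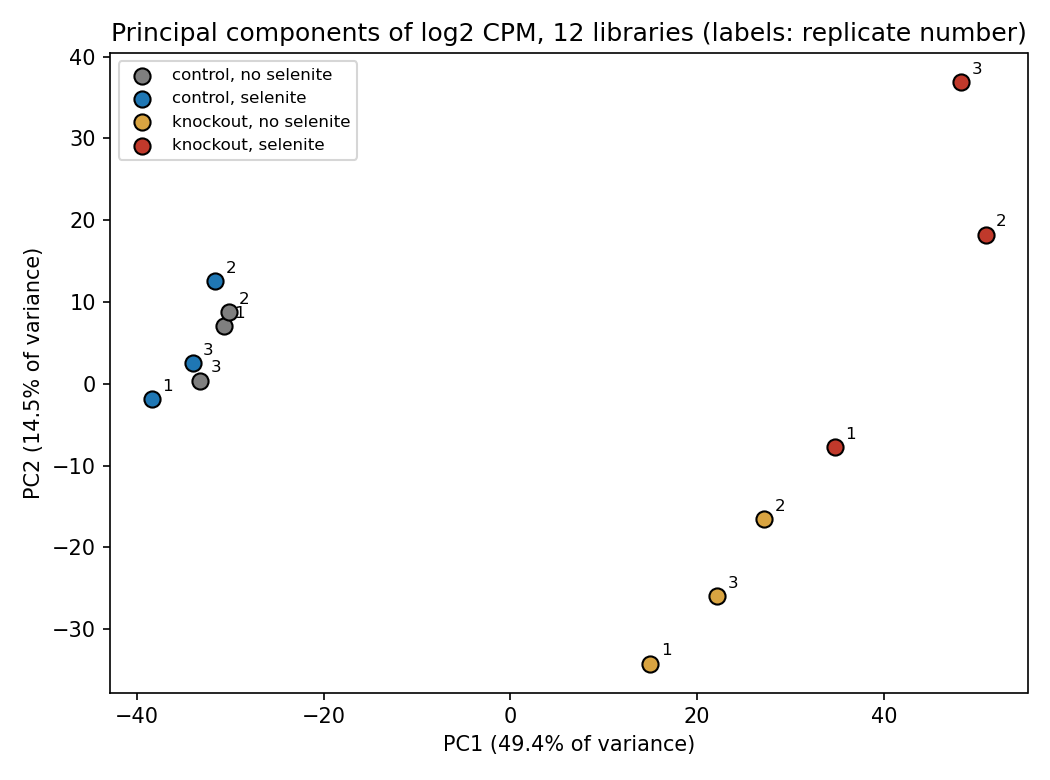
Principal components of log2 CPM for the 12 libraries, with the first component (49.4% of variance) on the x axis, the second (14.5%) on the y axis, colour for the group and a number for the replicate. The 6 control libraries lie at negative values of the first component and the 6 knockout libraries at positive values, and replicates 2 and 3 of the knockout with selenite have the lowest counts and the highest values on the second.

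FTSJ1 footprints were much lower in the knockout cells. The gene, on chromosome X at 48476199 to 48486364 (GRCh38), had 50.5 ± 4.72 CPM (SD, n = 3) in control cells without selenite and 2.59 ± 3.30 CPM in knockout cells, 5.13% of control. With selenite the levels were 61.0 ± 9.85 and 5.31 ± 6.10 CPM, 8.71% of control. The log2 fold changes were -4.41 ± 0.54 (SE) and -3.69 ± 0.53, with Benjamini-Hochberg adjusted p = 5.0e-05 and 1.1e-04 by edgeR quasi-likelihood tests. The first was -3.75 without knockout replicate 1 and -5.98 without knockout replicate 2 of the cells without selenite, and the second -4.39 without knockout replicate 3 with selenite. Knockout libraries held 0, 7 and 2 FTSJ1 counts without selenite and 6, 0 and 6 with it. The limit that 3 counts set was 1.97 to 5.99 CPM in the 6 knockout libraries. Those with 0 or 2 counts were below it and those with 6 or 7 above it. Knockout replicate 3 with selenite had 11.98 CPM, against a control mean of 61.0 CPM.

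The first comparison asked how knockout cells differed from control cells without selenite. Among the genes with the largest rises were MMP1, a collagenase, which went from 3.94 ± 1.53 to 435 ± 60.9 CPM (SD, n = 3), 107-fold. UTS2, the precursor of the peptide urotensin, had 1 count over the control libraries and 302 over the knockout libraries, a ratio per depth of 326 with an exact (Clopper-Pearson) 95% interval of 58.0 to 12908 that covers counting error only. GAP43, a growth-cone protein, rose 22.3-fold (34.1-fold without control replicate 2), and ID3, an inhibitor of helix-loop-helix transcription factors, rose 16.5-fold. FST, which encodes the activin-binding protein follistatin, fell from 915 ± 99.9 to 15.9 ± 3.41 CPM, and the cytokine gene IL24 fell from 131 ± 3.14 to 1.04 ± 0.934 CPM. The class II antigen-presentation genes HLA-DRB1 and HLA-DQA1 fell, with log2 fold changes of -5.31 and -5.32, the latter -6.09 without knockout replicate 2. HLA-DRB1 shares much of its sequence with HLA-DRB5, which fell by 4.86, and how reads shared by these paralogs were assigned is not stated. ANKRD30A had 407 counts in control cells and 0 in knockout cells, at least 126-fold lower with the limit set at 3 counts over the group.

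In all, 1240 genes rose and 1261 fell in knockout cells without selenite, of 10467 tested by edgeR quasi-likelihood at a Benjamini-Hochberg adjusted p under 0.05. DESeq2 called 840 higher and 816 lower, and thinning every library to the smallest total left 688 and 705. On simulated data of this comparison, with 134 genes called, the test recovered 65.2% of genes changed 2-fold and 95.2% of those changed 4-fold.

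The measured genes of melanocyte differentiation tended to be lower in knockout cells without selenite. Of 21 listed genes 10 are in the authors' table and 8 were tested. Of 8 measured members of the melanocyte differentiation list, 5 fell and 0 rose, 6 and 0 when adjusted over the list alone, and the median log2 fold change was -0.69 (camera, Benjamini-Hochberg adjusted p = 7.2e-04; adjusted p = 0.11 with an estimated correlation). MITF, the transcription factor that drives pigment-cell genes, fell by 1.32 ± 0.20 (SE) and SOX10, a neural-crest transcription factor, fell by 0.89 ± 0.11. ERBB3, a receptor of the EGF receptor family, fell by 0.80 ± 0.09 and the pigment-cell glycoprotein gene GPNMB fell by 1.14 ± 0.13. Markers of dedifferentiated melanoma moved both ways: of 23, 7 rose and 9 fell, and 8 rose and 9 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.56). TGFBI, an extracellular matrix protein gene, rose from 317 ± 5.87 to 1801 ± 113 CPM, whereas THBS1, which encodes thrombospondin, fell from 2418 ± 52.5 to 334 ± 11.5 CPM. The nerve growth factor receptor gene NGFR fell by 4.03 ± 0.25 and the receptor tyrosine kinase gene AXL by 2.12 ± 0.13.

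Cytosolic ribosomal protein genes were higher: 30 of 72 rose and 2 fell, 38 and 3 when adjusted over the list alone, with a median of 0.39 (camera, Benjamini-Hochberg adjusted p = 2.5e-05; adjusted p = 0.34 with an estimated correlation). RPS15A rose by 1.24 ± 0.17, RPL22 by 0.92 ± 0.14 and RPL14 by 0.61 ± 0.09. Of 32 cell cycle genes 10 fell and 0 rose, the same counts as when adjusted over the list alone, with a median of -0.21 (camera, Benjamini-Hochberg adjusted p = 0.033; adjusted p = 0.27 with an estimated correlation). That list call was lost without control replicate 2 (median -0.19, adjusted p = 0.076) or knockout replicate 2 (median -0.19, adjusted p = 0.058). The helicase subunit gene MCM2 fell by 0.63 ± 0.12 and the thymidine kinase gene TK1 by 0.62 ± 0.12.

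The other 19 tested lists did not pass in this comparison (camera, Benjamini-Hochberg adjusted p 0.098 to 0.88). Of all genes tested 23.9% passed, so members past the threshold do not by themselves set a list apart. Of 21 genes of MAPK output, the transcriptional response to ERK signalling, 4 rose and 9 fell: MYC rose 7.36-fold and EGR1 3.60-fold, whereas EPHA2 (-1.13) and DUSP4 (-1.17) fell on the log2 scale. Of 18 p53 targets 7 rose and 2 fell, among them the cell-cycle inhibitor gene CDKN1A, which rose 2.09-fold, and the exonuclease gene AEN, which rose 2.87-fold. Of 23 NRF2 targets 9 rose and 3 fell, NQO1, a quinone reductase, rising by 0.62 and PGD, an enzyme of the pentose phosphate pathway, by 0.65 on the log2 scale. Of 31 ATF4 targets 10 rose and 2 fell, and of 21 unfolded protein response genes 9 rose and 1 fell, among them PDIA4, a disulfide isomerase, which rose 1.74-fold. Of 16 cysteine homologues, enzymes related to selenoproteins that carry cysteine, 4 rose and 1 fell, with PRDX4 and PRDX6, both peroxiredoxins, up by 0.78 and 0.53. Of 18 ferroptosis regulators 5 rose and 1 fell, including the cystine transporter gene SLC7A11 (log2 fold change 0.70) and ACSL4 (0.58), which activates polyunsaturated fatty acids. The ACSL4 call was lost with every library thinned to the smallest total (log2 fold change 0.36, adjusted p = 0.11).

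Of 20 tRNA modification enzymes 4 rose and 2 fell, including WDR6, a partner of FTSJ1 in tRNA methylation, which rose by 0.49 ± 0.12. Of 12 genes of the selenocysteine machinery 1 fell, TRMT112, an activator of methyltransferases, by 0.51 ± 0.12. Of 48 nuclear genes of oxidative phosphorylation 11 rose and 3 fell, CYC1, the cytochrome c1 gene, rising 2.10-fold. Of 23 cholesterol synthesis genes 3 rose and 2 fell, of 31 interferon response genes 2 rose and 8 fell, of 27 hypoxia and glycolysis genes 7 rose and 6 fell, and of 13 metallothionein and heat shock genes 6 rose and 2 fell. Of 6 measured markers of other cell types 1 rose and 1 fell. Adjusted over the list alone, the higher and lower counts were 4 and 9 for MAPK output, 7 and 2 for p53 targets, 10 and 5 for NRF2 targets, 12 and 2 for ATF4 targets, 10 and 1 for the unfolded protein response and 5 and 1 for both cysteine homologues and ferroptosis regulators. They were 4 and 2 for tRNA modification enzymes, 0 and 1 for the selenocysteine machinery, 11 and 3 for oxidative phosphorylation, 4 and 3 for cholesterol synthesis, 4 and 8 for the interferon response, 8 and 6 for hypoxia and glycolysis, 6 and 2 for metallothioneins and heat shock and 1 and 1 for other cell types.

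Selenoprotein genes as a group did not pass the test between knockout and control cells without selenite. The median log2 fold change of 18 measured members was 0.00071 and the mean -0.017 (camera, Benjamini-Hochberg adjusted p = 0.81), with 3 higher and 2 lower, both over all genes and adjusted over the list alone. GPX4, the peroxidase that reduces lipid hydroperoxides, fell from 30.1 ± 7.59 to 14.4 ± 5.13 CPM (SD, n = 3; log2 fold change -1.07 ± 0.33, edgeR Benjamini-Hochberg adjusted p = 0.025). SELENOH, a nuclear selenoprotein gene, fell from 42.8 ± 3.78 to 23.5 ± 9.60 CPM (adjusted p = 0.0496). MSRB1, a methionine sulfoxide reductase, rose by 0.99 ± 0.27 (DESeq2 adjusted p = 0.059), SELENOI, an ethanolamine phosphotransferase, by 0.69 ± 0.11, and SELENON, an endoplasmic reticulum protein gene, by 0.52 ± 0.17. The GPX4 call was lost without any one of 5 libraries (control replicate 2 or 3 and knockout replicate 1 or 2, all without selenite, and knockout replicate 2 with selenite), with log2 fold changes of -1.32 to -0.78 over all left-out libraries and adjusted p up to 0.10. The SELENOH call was lost without any of 7 (all 3 control replicates and knockout replicates 1 and 2 without selenite, and replicate 2 of either genotype with it; adjusted p up to 0.17). That of SELENON was lost without any of 5 (all 3 control replicates and knockout replicates 1 and 2 without selenite; adjusted p up to 0.15). Of 6 stress-related selenoproteins, those known to respond most to selenium supply, 1 rose and 1 fell, and of 5 measured housekeeping selenoproteins 1 fell, the same as when adjusted over each list alone.

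The same comparison was made with selenite present, in 6 other libraries. MMP1 was again among the genes with the largest rises, from 2.24 ± 2.31 to 378 ± 74.6 CPM (SD, n = 3), 160-fold and 387-fold without control replicate 1. VGF, a secreted neuropeptide precursor gene, rose 22.4-fold from 152 to 3416 CPM. TGFBI rose 7.72-fold, MYC 7.76-fold and EGFR, the epidermal growth factor receptor gene, 7.18-fold. THBS1 fell by 2.60 ± 0.10 (SE) and HLA-DRB1 fell by 4.25 ± 0.20. PLAC8 had 157 counts over the control libraries and 2 over the knockout libraries, a ratio per depth of 0.0169 with an exact 95% interval of 0.00203 to 0.0621. Its fitted log2 fold change was -5.70, and -4.59 without knockout replicate 1 or -6.30 without knockout replicate 3. FST and IL24 had log2 fold changes of -4.87 and -5.04. Without knockout replicate 3 these were -5.79 and -7.25, and without knockout replicate 1 IL24 was at -3.88. Knockout replicate 3 held 81.9 CPM of FST, against 15.8 and 18.03 CPM in the other 2 knockout libraries, and 19.96 CPM of IL24, against 0 and 3.28 CPM. ANKRD30A had 24.0 CPM in that library and 0 in the other 2.

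With selenite 2228 genes were higher and 2266 lower in knockout cells (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 2777 in all without both shallow libraries. Across genes, which are not independent replicates, the knockout changes without and with selenite had Pearson r = 0.72 and Spearman rho = 0.61. The change with selenite had rho = 0.30 with the number of genes within 1 Mb, and the change without selenite 0.0017. With the gene density trend removed from each library, 4061 genes passed with selenite. Of the 2501 genes called without selenite, 1732 were called in the same direction with it, 893 higher and 839 lower. Independent calls would give 537, and 16 were called in the opposite direction. Both comparisons set the same knockout line against control, so any lasting difference of that line is shared, whatever its cause. With every library thinned to the smallest total the shared count was 978. On simulated data of this comparison, with 119 genes called, the test recovered 51.5% of genes changed 2-fold and 89.1% of those changed 4-fold.

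**Figure D2:**
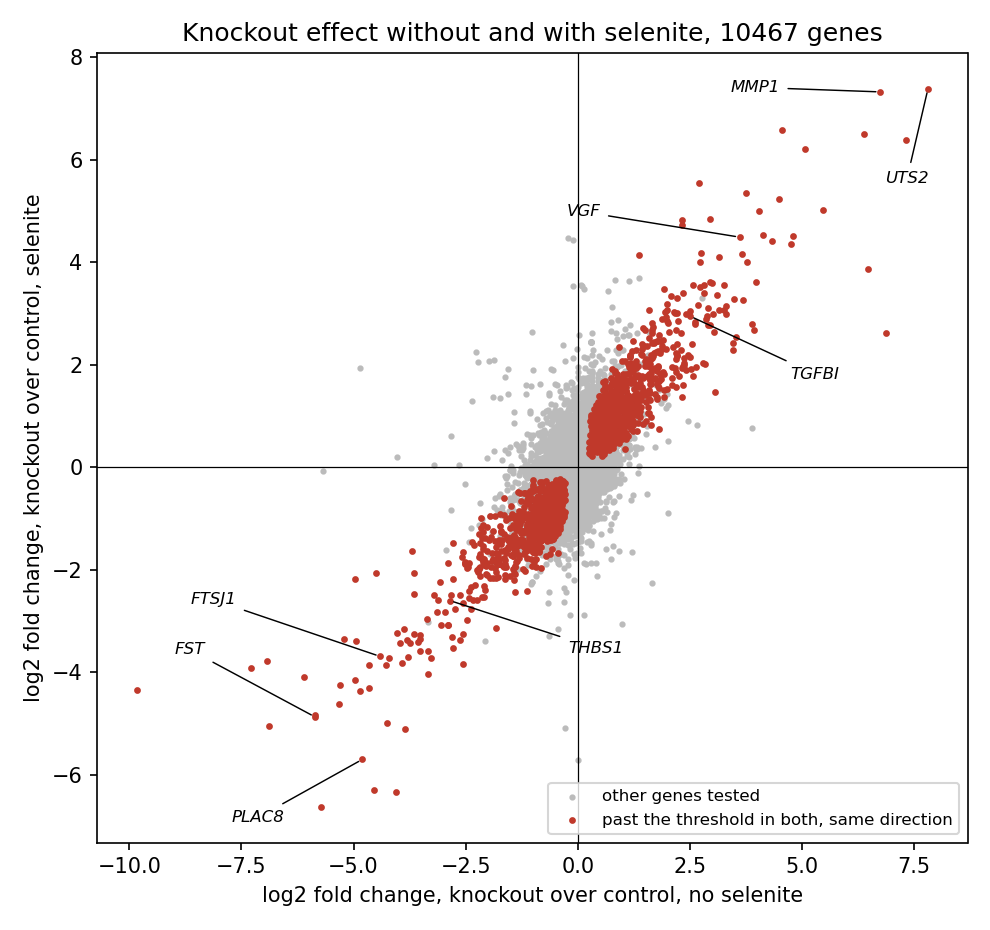
Log2 fold change of footprints between knockout and control cells without selenite (x axis) and with selenite (y axis) for 10467 genes, each point a gene. Red points are the 1732 genes past the threshold in both comparisons in the same direction, 893 higher and 839 lower in knockout cells.

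The gene groups that passed were the same 3 as without selenite. Of 72 ribosomal protein genes 44 rose and 4 fell, 45 and 4 when adjusted over the list alone, with a median of 0.52 (camera, Benjamini-Hochberg adjusted p = 3.0e-09; adjusted p = 0.31 with an estimated correlation), among them RPL27A, up by 1.39 ± 0.12, and RPLP0, up by 0.89 ± 0.09. Of 8 melanocyte differentiation genes 5 fell and 0 rose, also when adjusted over the list alone, with a median of -0.57 (camera, Benjamini-Hochberg adjusted p = 0.024; adjusted p = 0.31 with an estimated correlation). MITF fell by 1.22 ± 0.21, GPNMB by 1.58 ± 0.15 and EDNRB, the endothelin receptor gene of pigment cells, by 1.01 ± 0.19. SOX10, which fell without selenite, did not pass here, at 0.058 ± 0.11 (adjusted p = 0.71). Of 32 cell cycle genes 2 rose and 15 fell, 4 and 16 when adjusted over the list alone, with a median of -0.30 (camera, Benjamini-Hochberg adjusted p = 0.048; adjusted p = 0.31 with an estimated correlation). TOP2A, a DNA topoisomerase gene, fell by 1.06 ± 0.12 and CCNE2, a cyclin gene, by 1.60 ± 0.25. The cell cycle list call was lost without knockout replicate 2 with selenite (median -0.25, adjusted p = 0.083) or knockout replicate 1 without it (median -0.29, adjusted p = 0.054), and without both shallow libraries (median -0.24, adjusted p = 0.080). The other 19 lists did not pass (adjusted p 0.12 to 0.90), although CDKN1A and AEN rose 3.55-fold and 4.30-fold while MDM2, which encodes the ligase that degrades p53, fell by 1.05 ± 0.14.

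Selenoprotein genes did not pass as a group with selenite either, with a median of 0.20 over 18 members (camera, Benjamini-Hochberg adjusted p = 0.55). Over all genes 4 rose and 2 fell, and adjusted over the list alone 3 rose and 0 fell. SEPHS2, the selenophosphate synthetase gene, rose by 1.00 ± 0.17 (SE) from 49.2 ± 3.61 to 103 ± 30.4 CPM (SD, n = 3), SELENON rose 1.62-fold and SELENOI 1.28-fold, and MSRB1 rose 1.70-fold. TXNRD1, the cytosolic thioredoxin reductase gene, fell by 0.27 ± 0.11 and SELENOF, an endoplasmic reticulum selenoprotein gene, by 0.36 ± 0.14. These were -0.053 (adjusted p = 0.81) and -0.32 (adjusted p = 0.15) without both shallow libraries. Single libraries also decided calls. That of TXNRD1 was lost without control replicate 1 or 2 with selenite, any knockout replicate without it, or knockout replicate 2 or 3 with it (-0.28 to -0.18, adjusted p 0.051 to 0.25). That of SELENOF was lost without control replicate 1 or 2 or knockout replicate 3 with selenite, or knockout replicate 1 or 2 without it (-0.35 to -0.22, adjusted p up to 0.22). That of MSRB1 was lost without control replicate 1 or 2 or knockout replicate 1 with selenite (0.53 to 0.75, adjusted p 0.057 to 0.28). That of SELENOI was lost without control replicate 2 (0.28, adjusted p = 0.085) or knockout replicate 1 (0.21, adjusted p = 0.20) with selenite. GPX4 levels were 54.8 ± 14.5 and 59.2 ± 21.1 CPM in control and knockout cells, a log2 fold change of 0.0058 ± 0.28. GPX1, a cytosolic glutathione peroxidase gene, was at 0.75 ± 0.27 (adjusted p = 0.0503). It passed without knockout replicate 1 (1.03, adjusted p = 2.8e-06) or control replicate 2 (0.94, adjusted p = 0.020).

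The next comparison asked what 30 nM selenite did in control cells, and the genes that passed were both selenoprotein genes. TXNRD1, on chromosome 12 at 104215779 to 104350307 (GRCh38), rose from 220 ± 19.7 to 364 ± 23.5 CPM (SD, n = 3), 1.66-fold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 6.1e-04). SELENOW, a small selenoprotein gene on chromosome 19 at 47778703 to 47784682, rose from 1.88 ± 0.474 to 13.9 ± 3.80 CPM, 6.97-fold (adjusted p = 0.0055), on 8 counts without and 47 with selenite. Values that did not pass over all genes were 1.28 ± 0.29 (SE) for GPX1, 1.11 ± 0.25 for SELENOH and 0.87 ± 0.28 for GPX4. GPX1 passed without knockout replicate 1 with selenite (1.28, adjusted p = 7.7e-06), and SELENOH without control replicate 1 with selenite (1.31, adjusted p = 0.0095) or knockout replicate 3 without it (1.11, adjusted p = 0.0083). Without control replicate 1 or 3 without selenite, or control replicate 2 with it, 1 gene passed. With only the groups compared in the fit 4 genes passed. No gene fell, except 1 without control replicate 2 without selenite, 284 of 10467 genes had an unadjusted p under 0.05, and DESeq2 also called 2 genes, 1 of them shared with edgeR. On simulated data of this comparison, with 137 genes called, the test recovered 68.8% of genes changed 2-fold and 93.8% of those changed 4-fold. Only 2 genes passed in the data, where the adjusted threshold was thus stricter, so these shares do not carry over.

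As a group, the 18 selenoprotein genes rose with selenite in control cells, with a median log2 fold change of 0.45 (camera, Benjamini-Hochberg adjusted p = 1.2e-23; adjusted p = 1.8e-04 with an estimated correlation). Adjusted over the list alone, 7 rose and 0 fell, against 2 and 0 over all genes. The 6 stress-related members had a median of 1.00 (4 higher and 0 lower when adjusted over the list alone; adjusted p = 1.8e-04 with an estimated correlation), and the 5 housekeeping members a median of 0.32 (2 and 0; adjusted p = 0.0031 with an estimated correlation). The dedifferentiated melanoma list had a median of -0.10 with 0 genes called, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.021; adjusted p = 0.11 with an estimated correlation). The other 18 lists did not pass (adjusted p 0.23 to 0.98). The SELENOW call was lost without control replicate 1 (2.60, adjusted p = 0.19) or 3 (2.90, adjusted p = 0.055) of the cells without selenite and without control replicate 2 with selenite (2.59, adjusted p = 0.15), and with DESeq2 (2.88, adjusted p = 0.091). The dedifferentiated list call was lost without control replicate 1 without selenite (-0.092, adjusted p = 0.25) and without control replicate 1 (-0.11, adjusted p = 0.10) or 2 (-0.11, adjusted p = 0.060) with selenite.

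**Figure D3:**
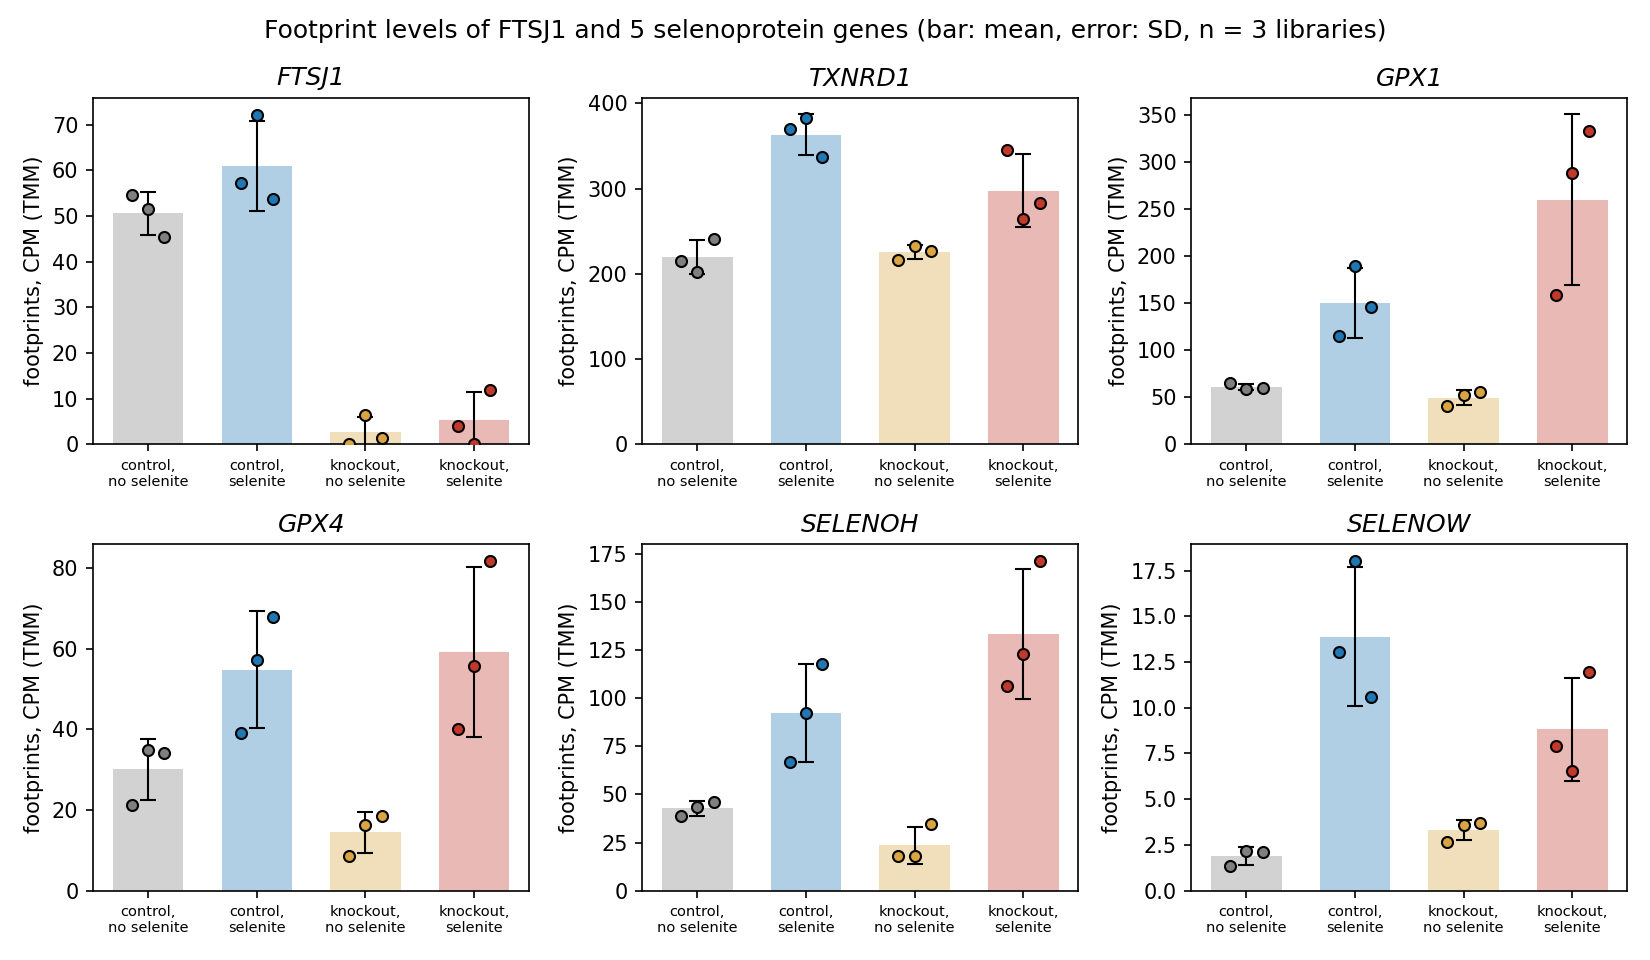
Footprint levels (CPM with TMM-scaled library sizes, y axes from 0) of FTSJ1 and 5 selenoprotein genes in the 4 groups; bars are means, error bars SD and points the 3 libraries, and error bars that would pass 0 end at the axis. TXNRD1 went from 220 to 364 CPM with selenite in control cells and from 226 to 298 CPM in knockout cells, and GPX1 from 61.3 to 150 CPM and from 49.6 to 260 CPM.

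In knockout cells, footprint levels of 9 of 18 selenoprotein genes measured rose with selenite, and 1 fell. SELENOH, on chromosome 11 at 57741491 to 57743550 (GRCh38), rose 5.45-fold from 23.5 ± 9.60 to 134 ± 33.8 CPM (SD, n = 3; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.9e-05). GPX1, on chromosome 3 at 49357176 to 49358353, rose 5.10-fold from 49.6 ± 8.06 to 260 ± 90.8 CPM (adjusted p = 0.0010), and GPX4, on chromosome 19 at 1103994 to 1106779, rose 3.87-fold from 14.4 ± 5.13 to 59.2 ± 21.1 CPM (adjusted p = 8.3e-04). SEPHS2 rose 1.70-fold and TXNRD1 1.33-fold. The median of the 18 genes was 0.69 (camera, Benjamini-Hochberg adjusted p = 1.3e-06; adjusted p = 0.0085 with an estimated correlation), with 9 higher and 1 lower over all genes and 11 higher and 1 lower when adjusted over the list alone.

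The 6 stress-related selenoproteins had a median of 1.56 in knockout cells (4 higher, 5 when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 1.3e-06; adjusted p = 0.0085 with an estimated correlation). The 5 housekeeping members had a median of 0.42 with 3 higher, also when adjusted over the list alone, and did not pass as a list (adjusted p = 0.069; adjusted p = 0.31 with an estimated correlation). That list passed without control replicate 1 (0.41, adjusted p = 0.049) or knockout replicate 3 (0.42, adjusted p = 0.042) of the cells without selenite, without knockout replicate 3 with it (0.45, adjusted p = 0.042), and without both shallow libraries (0.64, adjusted p = 0.022). SELENOW was at 1.34 ± 0.51 (SE; adjusted p = 0.055) and SELENOK at 1.46 ± 0.64 (adjusted p = 0.10), which passed without knockout replicate 2 without selenite (2.44, adjusted p = 0.023). Without both shallow libraries GPX4 was at 1.52 and SEPHS2 at 0.54. GPX1 had 158.7 CPM in knockout replicate 1 with selenite, against 288.5 and 333.4 CPM in the shallow libraries. SELENOH had 106.6 CPM there, against 122.9 and 171.7 CPM. SELENOT and TXNRD1 went the other way, with 88.2 against 50.8 and 45.9 CPM and 345.6 against 263.9 and 283.5 CPM. The TXNRD1 call was lost without knockout replicate 1 with selenite (0.26, adjusted p = 0.099). Those of SELENOT, a thioredoxin-fold protein gene (0.77 ± 0.23), and the mitochondrial reductase gene TXNRD2 (0.84 ± 0.24) were both lost without knockout replicate 1 without selenite (0.63 and 0.60, adjusted p = 0.12 for each). The SELENOT call was also lost without knockout replicate 1 with selenite (0.30, adjusted p = 0.41) and the TXNRD2 call without knockout replicate 3 with selenite (0.71, adjusted p = 0.061). That of SELENON (0.62 ± 0.17) was lost without knockout replicate 3 without selenite (0.48, adjusted p = 0.079) or replicate 2 with it (0.46, adjusted p = 0.098). That of GPX3 (1.79 ± 0.55) was lost without knockout replicate 2 or 3 of either condition (1.55 to 1.78, adjusted p 0.052 to 0.097). That of SELENOI (-0.32 ± 0.12) was lost without any library without selenite, control replicate 3 with it, or knockout replicate 2 or 3 with it (-0.33 to -0.24, adjusted p 0.053 to 0.21).

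**Figure D4:**
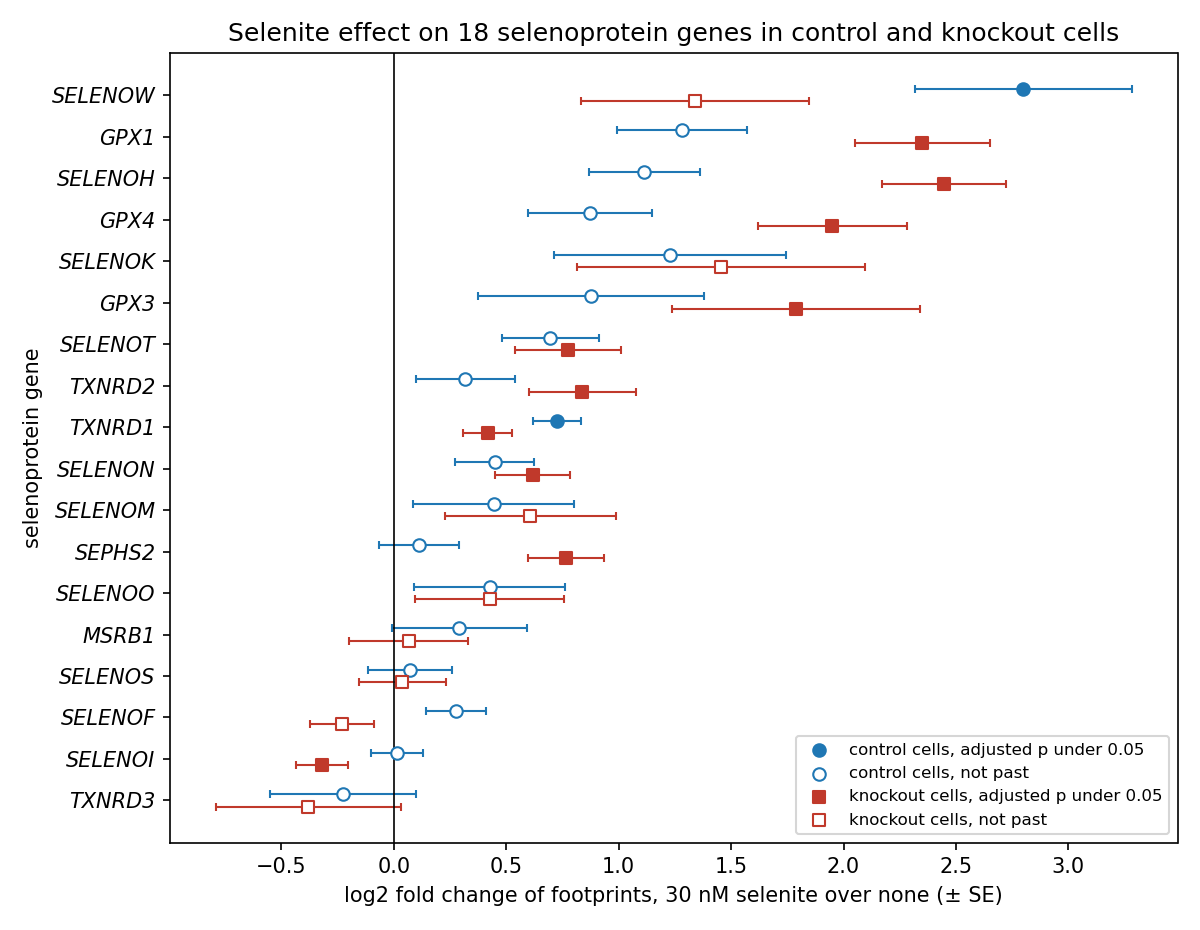
Log2 fold change with 30 nM selenite (x axis, ± SE) for each of 18 selenoprotein genes (y axis) in control cells (blue circles) and knockout cells (red squares); filled symbols passed an adjusted p under 0.05 over all genes, 2 in control cells and 10 in knockout cells. SELENOW had the largest value in control cells (2.80) and SELENOH in knockout cells (2.45).

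Many other genes also changed with selenite in knockout cells, in a group where the shallow libraries make up 2 of 3. RPL27A rose by 0.73 ± 0.11 (SE), the neural-crest gene SOX10 rose from 270 ± 43.5 to 493 ± 75.3 CPM (SD, n = 3), and the class I antigen-presentation gene HLA-B rose from 46.1 to 103 CPM. RPS26, a ribosomal protein gene, fell from 74.8 ± 10.5 to 13.4 ± 3.20 CPM, and TXN, which encodes thioredoxin, fell from 362 ± 37.3 to 186 ± 28.5 CPM. In all 1069 genes rose and 1080 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and DESeq2 called 1404. With the gene density trend removed from each library 1228 genes passed. Without both shallow libraries 54 genes passed, without knockout replicate 1 of the cells without selenite 802, and without replicate 2 or 3 of those with selenite 1044 or 1226. On simulated data of this comparison, with 118 genes called, the test recovered 51.6% of genes changed 2-fold and 89.4% of those changed 4-fold.

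Of 72 ribosomal protein genes 27 rose and 2 fell with selenite in knockout cells, 30 and 5 when adjusted over the list alone, with a median of 0.20 (camera, Benjamini-Hochberg adjusted p = 6.8e-05; adjusted p = 0.49 with an estimated correlation). Of 21 MAPK output genes 6 rose and 0 fell, also when adjusted over the list alone, with a median of 0.30 (adjusted p = 0.015; adjusted p = 0.38 with an estimated correlation), including the transcription factor gene ETV4, up by 0.77 ± 0.15 (SE). Of 27 hypoxia and glycolysis genes 9 rose and 2 fell, 11 and 2 when adjusted over the list alone, with a median of 0.17 (adjusted p = 0.036; adjusted p = 0.31 with an estimated correlation), the enolase gene ENO2 rising by 0.78 ± 0.14. Of 21 unfolded protein response genes 2 rose and 9 fell, also when adjusted over the list alone, with a median of -0.21 (adjusted p = 0.036; adjusted p = 0.49 with an estimated correlation). HSP90B1, a chaperone of the endoplasmic reticulum, fell by 0.62 ± 0.10 and PDIA3, a disulfide isomerase, by 0.69 ± 0.11. The last 2 list calls were lost without single libraries. That of hypoxia and glycolysis was lost without control replicate 2 without selenite (0.17, adjusted p = 0.051) or knockout replicate 1 with it (0.18, adjusted p = 0.095), and that of the unfolded protein response without knockout replicate 1 without selenite (-0.10, adjusted p = 0.078) or replicate 3 with it (-0.13, adjusted p = 0.11). Without both shallow libraries, which leaves 1 library in the group, ETV4 was at 0.73, ENO2 at 0.54, HSP90B1 at -0.43 and PDIA3 at -0.39. The other 16 lists did not pass (adjusted p 0.069 to 0.93).

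The last comparison, the interaction, asked whether the selenite effect differed between knockout and control cells. For selenoprotein genes as a group it did not pass, with a median difference of 0.12 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 0.65). Of 18 members 1 passed over all genes and 0 when adjusted over the list alone: SELENOH, which rose more in knockout cells by 1.33 ± 0.38 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.047). The differences were 1.07 ± 0.42 for GPX1, 1.08 ± 0.44 for GPX4, -1.46 ± 0.74 for SELENOW and -0.31 ± 0.15 for TXNRD1, none of which passed (adjusted p 0.16, 0.14, 0.21 and 0.21). Across the 18 genes, which are not independent replicates, the selenite changes in control and knockout cells had Pearson r = 0.65 and Spearman rho = 0.84, against -0.079 and -0.11 across all 10467 genes. Without knockout replicate 1 with selenite GPX1 (1.35, adjusted p = 1.9e-04), GPX4 (1.36, adjusted p = 0.023) and TXNRD1 (-0.47, adjusted p = 0.031) passed. The SELENOH call was lost without any control replicate or knockout replicate 1 or 2 of the cells without selenite, and without control replicate 2 or knockout replicate 2 or 3 with it (1.14 to 1.40, adjusted p 0.064 to 0.14) and without both shallow libraries (1.07, adjusted p = 0.26).

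Over all genes the interaction was higher for 394 and lower for 386 genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). With the gene density trend removed from each library 342 genes passed, and with every library thinned to the smallest total 474. With the knockout labels kept, 7 of 20 assignments of the selenite labels of the control libraries, the real one included, gave as many genes. SOX10 went up more with selenite in knockout cells by 0.95 ± 0.16 (SE) and RPL27A by 0.90 ± 0.16, whereas TXN went down more by -0.95 ± 0.16 and RPS26 by -2.16 ± 0.36. Of 72 ribosomal protein genes 18 were higher and 1 lower, 19 and 2 when adjusted over the list alone, with a median of 0.19 (camera, Benjamini-Hochberg adjusted p = 0.0067; adjusted p = 0.72 with an estimated correlation). That list call was lost without control replicate 3 without selenite (0.17, adjusted p = 0.091) or control replicate 1 with it (0.13, adjusted p = 0.17). The other 21 lists did not pass (adjusted p 0.052 to 1.0). Without both shallow libraries, which leaves 1 library in the group, SOX10 was at 0.70, RPL27A at 0.81, TXN at -0.74 and RPS26 at -2.06. Leaving out control replicates 1, 2 and 3 without selenite in turn gave 351, 335 and 468 genes, control replicates 1 and 3 with selenite 272 and 489, knockout replicates 1 and 3 without selenite 123 and 422, and knockout replicates 1, 2 and 3 with selenite 1707, 205 and 298. On simulated data, with 78 genes called, the test recovered 35.9% of genes whose difference was 2-fold and 71.9% of those at 4-fold.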

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

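All tests of technical sources given here were chosen after the data had been seen. For depth, for the gradient between control libraries and for gene density, the expected outcome was written before the result of the test. For the fits without both shallow libraries (knockout with selenite, replicates 2 and 3), the gradient and the gene density trend as whole causes, and all regroupings of the libraries, it was written after the results.

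Each result given here differed between genotypes in its response to selenite by a test of the difference itself, the interaction. It passed for 780 genes, from 123 without knockout replicate 1 without selenite to 1707 without knockout replicate 1 with it. The list of cytosolic ribosomal proteins passed with a median of 0.19 at the preset correlation between genes, but not with an estimated one. It also did not pass without control replicate 3 without selenite (0.17) or control replicate 1 with it (0.13). Of the genes the text names beyond the selenoproteins, larger values with selenite in knockout cells were found for PAM16 (2.76), RPL37 (2.36), HLA-B (1.23), ENO2 (1.00), ETV4 (0.97), SOX10 (0.95), RPL27A (0.90), CDKN1A (0.76), HSPA1B (0.70), HSPB1 (0.70), TKT (0.68), DUSP4 (0.68), MCM2 (0.66), TK1 (0.61), RPLP0 (0.53) and TGFBI (0.44), all as log2 differences. Smaller values were found for RPS26 (-2.16), RRAS2 (-1.94), HIGD1A (-1.66), CCNE2 (-1.16), TXN (-0.95), ACSL4 (-0.79), MDM2 (-0.69), PDIA3 (-0.57), HSP90B1 (-0.54) and TOP2A (-0.54). SELENOH, at 1.33, was the 1 selenoprotein gene of 18 among them. Of these 27 genes, 16 lost their call without 1 library or another, and all 27 kept their direction in each case. They also kept it without both shallow libraries (knockout with selenite, replicates 2 and 3). Calls lost in that fit do not show whether those libraries carry the differences, since it leaves 1 library in the group. The interaction was not refitted without other pairs of that group, but selenite in knockout cells was, as given below. TGFBI did not pass without control replicate 1, 2 or 3 or knockout replicate 1 or 3 without selenite, or control replicate 1, 2 or 3 or knockout replicate 2 with it (0.39 to 0.47). TOP2A did not pass without control replicate 1, 2 or 3 or knockout replicate 1 or 3 without selenite, or control replicate 1 or 3 or knockout replicate 2 or 3 with it (-0.57 to -0.38). DUSP4 did not pass without control replicate 1 or 2 or knockout replicate 1 or 3 without selenite, or control replicate 1 or 3 or knockout replicate 2 or 3 with it (0.58 to 0.68). PDIA3 did not pass without control replicate 2 or 3 or knockout replicate 1 or 3 without selenite, or control replicate 1 or 2 or knockout replicate 2 or 3 with it (-0.60 to -0.46). SELENOH did not pass without control replicate 1, 2 or 3 or knockout replicate 1 or 2 without selenite, or control replicate 2 or knockout replicate 2 or 3 with it (1.14 to 1.40). TK1 did not pass without control replicate 1, 2 or 3 or knockout replicate 1 or 3 without selenite, or control replicate 1 or knockout replicate 2 with it (0.53 to 0.66). CCNE2 did not pass without control replicate 1 or knockout replicate 1 or 3 without selenite, or control replicate 1 or knockout replicate 1 or 2 with it (-1.16 to -0.995). HSPA1B did not pass without control replicate 2 or 3 or knockout replicate 1 without selenite, or control replicate 1 or knockout replicate 2 or 3 with it (0.56 to 0.69). RPL37 did not pass without control replicate 2 or 3 or knockout replicate 1 without selenite, or control replicate 1 or 3 or knockout replicate 2 with it (2.14 to 2.34). HSP90B1 did not pass without control replicate 2 or knockout replicate 1 without selenite, or control replicate 1 or knockout replicate 2 or 3 with it (-0.51 to -0.42). MDM2 did not pass without control replicate 3 or knockout replicate 1 or 3 without selenite, or control replicate 1 or knockout replicate 3 with it (-0.66 to -0.60). HSPB1 did not pass without control replicate 1 or knockout replicate 1 without selenite, or control replicate 1 or knockout replicate 2 with it (0.59 to 0.65). CDKN1A did not pass without control replicate 2 without selenite, or control replicate 1 or knockout replicate 2 with it (0.66 to 0.72). MCM2 did not pass without control replicate 2 or knockout replicate 1 without selenite, or knockout replicate 2 with it (0.61 to 0.65). RRAS2 did not pass without knockout replicate 1 without selenite, or control replicate 1 or knockout replicate 2 with it (-1.85 to -1.49). ACSL4 did not pass without knockout replicate 1 without selenite (-0.71). HIGD1A was at -2.45 without knockout replicate 1 with selenite. HSPA1B has a near-identical paralog, and how reads shared with it were assigned is not stated.

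The first pattern weighed was that 2149 genes passed with selenite in knockout cells (802 without knockout replicate 1 without selenite, 1044 and 1226 without replicates 2 and 3 with it) and 2 in control cells (1 without control replicate 1 or 3 without selenite or control replicate 2 with it). Tables argued against depth, since 1541 and 2 genes passed with every library thinned to the smallest total. They also argued against a gene density trend as the whole cause, since 1228 genes passed with it removed, 935 of them shared with the 2149. With the control gradient as a covariate 1803 genes passed, 1765 of them shared, which does not decide on that gradient. Its axis was the difference of 2 control libraries with selenite. These scored -2.18 and 2.04 on it, against -0.30 to 0.87 for the knockout libraries, so the covariate could take out only part of a gradient. Other values left technical sources open in part: without both shallow libraries 54 genes passed, against 1614 and 1336 without replicate 1 and one of them, the knockout selenite change had Spearman rho = 0.30 across genes with the difference of 2 control libraries (-0.15 to 0.20 for the other 5 pairs, and only just past the bound written before the test), and rho = 0.42 with the number of genes within 1 Mb (-0.069 for selenite in control cells, -0.15 to 0.27 between replicates of one group). A candidate explanation is that the shallow libraries differ from the others in handling or base composition, which could not be measured without sequence. A response of knockout cells to selenite, which the design names, stays open and cannot be separated here, because the shallow libraries are 2 of the 3 in its group.

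The second pattern weighed was the rise of selenoprotein genes with selenite in knockout cells, with a median of 0.69. Without both shallow libraries the median was 0.66, which argues against these libraries as the source for the list as a whole. With the control gradient as a covariate the median was 0.68 and the list passed, but that covariate could take out only part of a gradient. With the gene density trend removed the median was 0.55. An effect of selenite on selenoprotein footprints in knockout cells may account for it, as in control cells (median 0.45), but this stays a hypothesis, since mRNA level and translation were not separated. Whether the size of the rise differs between genotypes was tested by the interaction, which did not pass for the list.

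Regroupings bear on whether chance can be excluded. With 6 libraries there are 10 splits into groups of 3, too few for a share under 0.05. For the knockout comparisons the real split, with 2501 genes without and 4494 with selenite, was the 1 split of 10 with as many, and the highest of the other splits gave 0 genes in both. For selenite in knockout cells it was the 1 of 10, with 2149 genes against 20 in the highest other, and for selenite in control cells 4 of 10 splits gave as many as the real 2, the highest other giving 18. For the interaction, 2 of 100 draws of the selenite labels within each genotype, the real one included, gave 780 or more genes, and the highest other gave 1092. These draws test selenite in either genotype, not the difference, so they do not decide whether chance accounts for it. With the knockout labels kept, 7 of 20 assignments of the control labels, the real one included, gave 780 or more genes, the other 19 ranging from 153 to 1415. With the control labels kept, the real assignment of the knockout labels was the 1 of 20 with as many, too few for a share under 0.05. The highest other gave 324, with the knockout labels swapped, which keeps the same split. The next highest gave 16. The number of interaction genes thus depended on the split of the knockout libraries and also moved with the labels of the control libraries. A response of knockout cells to selenite and a technical structure of the knockout libraries were not separated.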

How the results depend on the processing

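The fits without both shallow libraries, with thinned libraries, with identical genes taken once, with the gradient covariate and with the gene density trend removed were chosen after the data were seen, and all other alternatives were planned. No result reversed its direction past the threshold under any alternative. Of 5399 values of named genes under an alternative 5078 kept their side of the threshold and, where they passed, their direction, 281 no longer passed and 40 passed newly, and of 415 values of lists 354 kept, 51 no longer passed and 10 passed newly. Without both shallow libraries the number of genes was 10 for the interaction, 54 for selenite in knockout cells and 2777 for the knockout with selenite. That fit leaves 1 library in its group, which is assumed to vary like the others. Thinned to the smallest total, with 8212 genes tested and fewer counts, it was 474 for the interaction, 1393 for the knockout without selenite and 978 for genes changed by the knockout in both conditions. With the gene density trend removed it was 342 for the interaction and 1228 for selenite in knockout cells. DESeq2 gave 1656 for the knockout without selenite and 1404 for selenite in knockout cells. For selenite in control cells the stricter filter gave 1 gene, only the groups compared 4 and the replicate block 5. The cause of these shifts was not tested beyond what the constructions show. The share of interaction genes that were higher, 50.5% with TMM, was 40.2% with library totals only, 56.8% with the stricter filter and 62.0% with thinned libraries. For selenite in knockout cells it was 49.7%, and 40.2%, 55.7% and 57.8% in these fits.

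With the replicate block the interaction gave 1268 genes, the knockout 2811 without and 4779 with selenite, and selenite in knockout cells 2603. Whether equal numbers pair the libraries is open: over 5703 abundant genes, all 6 knockout libraries correlated best with the library of their own number across selenite (r = 0.37, 0.24 and 0.12), and over all 10467 genes 4 of 6 did (0.23, 0.18 and 0.023). The choice to report unblocked fits was kept after these values and the blocked counts had been seen.

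Leaving out each library in turn gave 123 to 1707 genes for the interaction (without knockout replicate 1 without and with selenite), 802 to 2758 for selenite in knockout cells (without the same libraries), 1 to 3 for selenite in control cells, 1882 to 2723 and 3674 to 4491 for the knockout without and with selenite, and 1364 to 1759 for genes changed in both. FTSJ1 ranged from -5.98 to -3.75 without and from -4.39 to -3.28 with selenite. The selenoprotein median ranged from -0.11 to 0.052 and from 0.093 to 0.32 for the knockout without and with selenite, from 0.36 to 0.56 and from 0.62 to 0.80 for selenite in control and knockout cells, and from -0.0015 to 0.29 for the interaction. SELENOP, with 1 or 2 counts per group, was not tested, and whether depth or low expression accounts for that was not determined.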

Other observations

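The test of selenoprotein groups against each other, the gene families and the genes followed in single libraries were all chosen after the results were seen, and the criterion for the first was revised after its p was known: a p of 0.05 or more was first to count against the hypothesis, and was then taken to decide nothing.

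Gene families were formed by symbol and compared with all other genes by camera, adjusted by the Benjamini-Hochberg method over 129 families. HLA genes, which encode antigen-presenting proteins, had a median log2 fold change of -2.38 between knockout and control cells without selenite, with 12 of 17 lower and 0 higher (adjusted p = 3.6e-34; adjusted p = 0.067 with an estimated correlation). With selenite the median was -2.46, with 11 lower and 3 higher (adjusted p = 2.9e-13; adjusted p = 0.73 with an estimated correlation). Core and linker histone genes, which package DNA, had a median of 0.52 with selenite in knockout cells, with 52 of 68 higher and 1 lower (adjusted p = 1.4e-25; adjusted p = 0.80 with an estimated correlation), in the comparison that holds the shallow libraries. Collagen genes had a median of 0.53 there, with 7 of 16 higher and 0 lower (adjusted p = 2.0e-05, and 0.80 with an estimated correlation). Other families also passed and are not all given. For HLA genes with selenite in knockout cells the median was 0.51, with 4 of 17 higher and 0 lower (adjusted p = 0.014, and 0.825 with an estimated correlation). In control cells PCDHA genes had a median of -0.26 with selenite and 0 called (adjusted p = 1.0e-04, and 0.98 with an estimated correlation).

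A hypothesis from selenium biology is that stress-related selenoproteins respond more to selenium than housekeeping ones. Mean log2 changes with selenite were 1.18 for 6 stress-related and 0.39 for 5 housekeeping genes in control cells, and 1.46 and 0.52 in knockout cells. By exact permutation over 462 arrangements of the genes the two-sided p was 0.0779 in control cells and 0.130 in knockout cells (one-sided 0.0390 and 0.0649; the side was not fixed beforehand). The direction may be as the hypothesis has it, but these p-values do not decide it, and genes are not independent replicates.

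In knockout replicate 3 with selenite, 11 genes lost in the knockout, chosen from the libraries without selenite, had a median of 11.3% of their control level (0 to 243%), against 1.86% (0 to 47.9%) and 3.02% (0 to 9.57%) in replicates 1 and 2. For 5 genes gained in the knockout the median was 71.2% of the knockout level without selenite (50.3% to 212%), against 98.7% (84.7% to 155%) and 105% (84.5% to 207%), so members went both ways. No source was tested. PTPRJ, a receptor phosphatase gene, ranged from 64.4 to 3736 CPM over the 12 libraries, and from 497 to 2565 CPM within the control libraries without selenite. Genes with identical counts in all libraries formed 20 sets of 53 genes, among them 6 of 9 tested CT45A genes, of which all 9 were called lower with selenite in knockout cells, so these are not separate measurements.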
